A study of Mus musculus with 4 samples.

How the data were processed

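Gene expression was measured in endothelial cells derived from mouse induced pluripotent stem cells (iPSCs), which are adult cells reprogrammed to an embryo-like state. The cells came from 2 healthy control mice and 2 mice with diet-induced obesity (DIO), 1 array per mouse. Per the labels, the mice were aged 24 weeks, the cells were grown in an endothelial medium and trypsinized before total RNA was isolated, and biotin-labelled RNA was hybridized to Affymetrix mouse expression arrays. The labels call the samples biological duplicates and their titles name a mouse 1 and a mouse 2 in each group, which set the groups and the replicate numbers. The cell type entry of the labels reads iPSC while the titles name derived endothelial cells, and no label mentions a sort, so how pure the endothelial cells were is not known. Nothing says whether each mouse gave 1 or more iPSC lines, so the p-values of single genes measure the spread between these samples. Part of that spread may be technical. The p-values of gene lists at a preset correlation, described below, do not measure it.

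The values used were the log2 expression levels per probe set that the authors deposited as 1 table. The background correction, normalization and summary method behind them are not given in the sources used here. The scale was taken from the values, which ran from 2.59 to 14.56. A natural log of a 16-bit signal cannot exceed 11.09, and no value was negative. The medians over all probe sets were 5.63 and 5.65 in control 1 and 2 and 5.61 and 5.61 in DIO 1 and 2, so the columns had been brought to similar scales and genes were not centred. No detection calls were used here, so how far a dim probe set lies above background is unknown. The number of arrays, 2 per group, limits the precision: the 95% confidence interval of a gene's log2 difference reached a median of 0.456 to either side.

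Of 45101 probe sets, 64 manufacturer control probe sets were left out of the tests and used only as quality measures. Gene names came from the platform annotation, in which 34945 probe sets had 1 gene symbol, 932 had several and 9160 were not listed. By gene number, 34741 of those with 1 symbol matched a RefSeq table of the GRCm38.p6 assembly, and 0 changed their symbol. No build underlies the deposited values, so no coordinates are given. Each of 18193 genes was represented by the probe set with the highest mean over the 4 arrays among those naming that gene alone, with no filter on dim probe sets.

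DIO was compared with control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes, a threshold of 0.05 and a further count at a log2 difference of 1 or more. Differences are DIO mean minus control mean, on the log2 scale. The 34 gene lists held 705 members, of which 659 were measured. They covered endothelial identity and function, inflammation and interferon response, metabolism, stress, growth, signalling, imprinted, sex-linked and positional genes, and markers of other cell types. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 34 lists. It was tested again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. At the preset correlation, genes rather than arrays are the units of the camera test, so its p does not measure the spread between mice. With an estimated correlation the test has only the residual degrees of freedom of 4 arrays. A call lost there does not by itself show that the list's genes move together.

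The groups, the tests, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 10 genes per direction past the threshold with both DIO arrays on the same side of both controls and the brighter group's mean above the median of gene means, 7.09. Where fewer passed, those with the smallest p filled the places and are said not to have passed. Clone and predicted-gene names were left out. It also took, of each list, up to 4 members past the threshold or, where fewer than 2 passed, the brightest, and always Nos3, Pecam1, Cdh5, Kdr and Pou5f1. Lists of epidermal, further pluripotent cell, and trophoblast and placental genes were added later.

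The fit was tested on simulated arrays with 18193 genes, of which 200 were changed, in 5 runs. At a true log2 change of 1 it recovered 0% of them, at 2 it recovered 60.9% with 6.6 false calls per run, and at 3 it recovered 86.9% with 9.2 false calls. Of unchanged genes, 4.97% had an unadjusted p below 0.05. The simulated noise was independent between genes and had the same spread on every array. Unlike the data, it thus held no array standing apart and no genes moving together. Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, averaging a gene's probe sets, testing each probe set, a trended and robust eBayes, limma's treat against a fold change of 1.2, thresholds of 0.1 and 0.01, the replicate number as a block, and leaving out each array in turn. Array weights and a run without the genes standing apart in control 2 were added after seeing the data. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.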

Results

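The data were 4 arrays of iPSC-derived endothelial cells, 2 from healthy control mice and 2 from DIO mice, each with 1 log2 expression level for 18193 genes. The titles call the cells endothelial while the cell type entry of the labels reads iPSC, so "endothelial" here follows the titles. The comparison asked which genes differ between endothelial cells derived from obese and from healthy animals. Arrays are called control 1, control 2, DIO 1 and DIO 2 after the mouse they came from.

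Interferon response genes were lower in the DIO cells than in either control. Of 24 measured members, 21 had a lower DIO mean and 19 had both DIO arrays below both controls, with a median difference of −0.52 (camera, adjusted p = 4.24e-10). The call was lost with an estimated correlation, which was 0.159 for this list (adjusted p = 0.847, unadjusted p = 0.0734 by camera in limma). It was also lost with fry (adjusted p = 0.543), and no member passed alone. Rsad2, an antiviral enzyme, was at 12.98 and 12.64 in the controls and 11.99 and 12.11 in DIO, a difference of −0.76 ± 0.17 (SE). Ifi35 differed by −0.60 ± 0.19 and Oas1a, a sensor of double-stranded RNA, by −0.42 ± 0.18. The 3 members with a higher DIO mean were Bst2 at 0.03 and, named after their values were seen, Oas2 at 0.24 and Cmpk2 at 0.35. Bst2 turned to −0.12 without control 2 and −0.06 without DIO 2, and Oas1a was at −0.26 without control 1. The list's median was −0.45 against control 1 and −0.48 against control 2, with 21 members lower in each case, and without control 2 its adjusted p was 2.56e-05. A measure of the RNA also separated the groups: 18S ribosomal RNA averaged 12.60 and 12.65 in the controls and 12.30 and 11.96 in DIO, whichever list is compared.

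**Figure D1:**
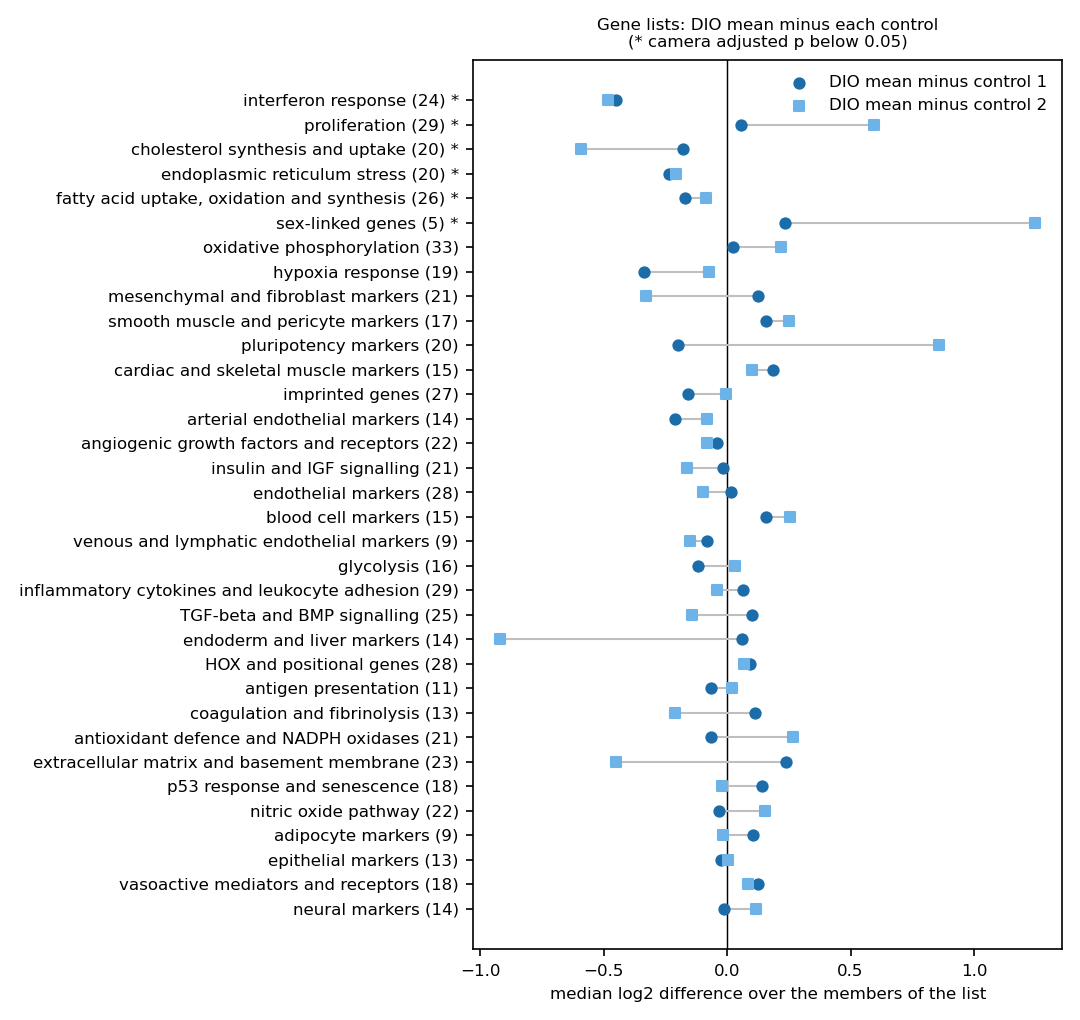
Median log2 difference over the measured members of each of 34 gene lists (vertical axis, with the number of members), as the mean of the 2 DIO arrays minus control 1 (circles) and minus control 2 (squares); grey lines join both values of a list and asterisks mark lists past a camera adjusted p of 0.05. The interferon response list lies at −0.45 and −0.48, while proliferation lies at 0.06 against control 1 and 0.59 against control 2.

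Genes of cell division had higher DIO means in 29 of 29 measured members, with a median difference of 0.35. The adjusted p by camera was 9.60e-07, and 0.847 with an estimated correlation, which was 0.802 for this list. Both DIO arrays lay above both controls for 14 of them. Cdc20, an activator of the anaphase-promoting complex, differed by 0.50 ± 0.15, and the replication licensing genes Mcm5 and Mcm7 by 0.52 ± 0.28 and 0.22 ± 0.25. Pcna, the sliding clamp of DNA polymerase, differed by 0.04 ± 0.19. Without control 2, Mcm5 was at 0.16, Mcm7 at −0.07 and Pcna at −0.16, and Pcna was at −0.07 without DIO 1. The median difference was 0.06 against control 1, with 19 members higher, and 0.59 against control 2, with 29 higher, and without control 2 the adjusted p was 0.113. In control 2, where 37 of 38 epidermal genes were highest among the arrays, 28 of the 29 members were lower than in control 1, by a median of −0.49. All 20 pluripotency genes were also lower in control 2 than in control 1, as they were in DIO 2 than in DIO 1.

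Cholesterol synthesis genes were lower in DIO in 19 of 20 measured members, with a median of −0.34 and both DIO arrays below both controls for 14. By camera the adjusted p was 9.54e-06, and 0.847 with an estimated correlation, which was 0.551 for this list. Hmgcs1, which makes the precursor of mevalonate, differed by −0.31 ± 0.22, Fdps by −0.47 ± 0.25, Fdft1, the squalene synthase, by −0.40 ± 0.18, and Sqle, the squalene epoxidase, by −0.30 ± 0.14. Mvd was the exception at 0.22, named after its value was seen. The median was −0.18 against control 1 and −0.59 against control 2. Without control 2 the adjusted p was 0.253, with Hmgcs1 at −0.04, Fdps at −0.16 and Fdft1 at −0.23. In control 2, which stood apart by its epidermal genes, 18 of the 20 members were higher than in control 1, by a median of 0.44.

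Genes of the endoplasmic reticulum stress response were lower in DIO in 15 of 20 members, with a median of −0.20. By camera the adjusted p was 0.00129, and 0.847 with an estimated correlation, which was −0.008 for this list. The chaperone Hspa5 differed by −0.23 ± 0.12 and the transcription factor Xbp1 by −0.41 ± 0.13, while the chaperones Calr and Hsp90b1 were among the 5 members with a higher DIO mean, at 0.16 ± 0.18 and 0.24 ± 0.23, which turned to −0.05 without DIO 2 and −0.02 without control 1. The other higher members, named after their values were seen, were Asns at 0.18, Herpud1 at 0.12 and Dnajb9 at 0.01. The list's median was −0.24 against control 1, −0.21 against control 2 and −0.11 after centring. The adjusted p was 0.0957 without control 2.

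Fatty acid genes had lower DIO means in 19 of 26 members, with a median of −0.16. By camera the adjusted p was 0.0283, and 0.847 with an estimated correlation, which was −0.005 for this list. The fatty acid binding proteins Fabp5 and Fabp3 differed by −0.39 ± 0.56 and 0.15 ± 0.18, the desaturase Scd2 by −0.26 ± 0.25 and the lipid droplet protein Plin2 by −0.13 ± 0.13. Without control 2, Fabp5 was at 0.37, Fabp3 at −0.03 and Scd2 at 0.02, and without DIO 1 Plin2 was at −0.07. The median was −0.17 against control 1, −0.09 against control 2, −0.10 after quantile normalization and −0.07 after centring. The adjusted p was 0.246 without control 2, 0.107 without DIO 1, 0.0647 after quantile normalization, 0.0682 without the dimmest genes and 0.0996 with averaged probe sets.

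Of the 5 measured sex-linked genes, 4 had a higher DIO mean, with a median of 1.12, which is the value of Kdm5d. By camera the adjusted p was 0.0283, and 0.847 with an estimated correlation, which was 0.384 for this list. The list pools Y-linked genes with Xist and Tsix, so a direction over the whole of it has no single meaning. The Y-linked genes Eif2s3y and Uty differed by 1.15 ± 0.14 and 1.68 ± 0.29. They passed when adjusted over the list alone, but not over all genes (adjusted p = 0.728 in limma). In any other list 0 genes passed in this way, but with 5 measured genes this was the smallest list, so its adjustment was the lightest. Kdm5d, also on the Y chromosome, was at 5.38 and 3.6 in the controls and 5.56 and 5.67 in DIO, and both its other probe sets had the opposite sign. Xist, the RNA that silences an X chromosome, differed by −0.42 ± 0.45, which turned to 0.20 without control 1, and its antisense partner Tsix by 0.08. The list's median was 0.24 against control 1, again the value of Kdm5d, and 1.25 against control 2. The adjusted p was 0.17 without control 2 and 0.0996 with averaged probe sets, where the median was 0.34.

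Among single genes, those lower in DIO with the smallest p included Lipg, the endothelial lipase, which was at 10.76 and 10.76 in the controls and 9.26 and 9.52 in DIO, a difference of −1.37 ± 0.15. Pstpip2, an adaptor of the actin cytoskeleton, differed by −1.63 ± 0.15, Fam124a by −1.28 ± 0.15, the magnesium transporter Slc41a2 by −1.14 ± 0.16 and Otulinl by −1.08 ± 0.15. The organic cation transporter Slc22a4 differed by −1.06 ± 0.16, the secreted factor Metrnl by −1.03 ± 0.14, the transcription factor Dmrta2 by −1.03 ± 0.12, the kinase Wnk4 by −1.02 ± 0.13 and the adenylyl cyclase Adcy9 by −0.88 ± 0.12. Higher in DIO were the zinc finger genes Zfp979 at 1.64 ± 0.24 and Zfp51 at 0.71 ± 0.14, Eif2s3y as above, the chromatin remodeller Hells at 1.07 ± 0.19, the amino acid transporter Slc7a8 at 1.06 ± 0.13 and Crxos at 0.96 ± 0.18. Pltp, which transfers phospholipids between lipoproteins, differed by 0.86 ± 0.14, Zbtb44 by 0.86 ± 0.16, Ager, the receptor for advanced glycation end products, by 0.79 ± 0.15 and the mitotic kinesin Kif18a by 0.76 ± 0.12. None of these 20 genes passed (limma, adjusted p = 0.728 for each). Without control 1, Eif2s3y, Hells and Pstpip2 did (adjusted p = 0.0386, 0.0421 and 0.0362). Other probe sets of Kif18a, Hells and Zbtb44 had the opposite sign. With the probe sets of a gene averaged, the differences were 0.30 for Kif18a, 0.25 for Zbtb44, 0.48 for Hells, 0.52 for Crxos, 0.52 for Pltp, 0.68 for Eif2s3y and −0.57 for Otulinl.

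**Figure D2:**
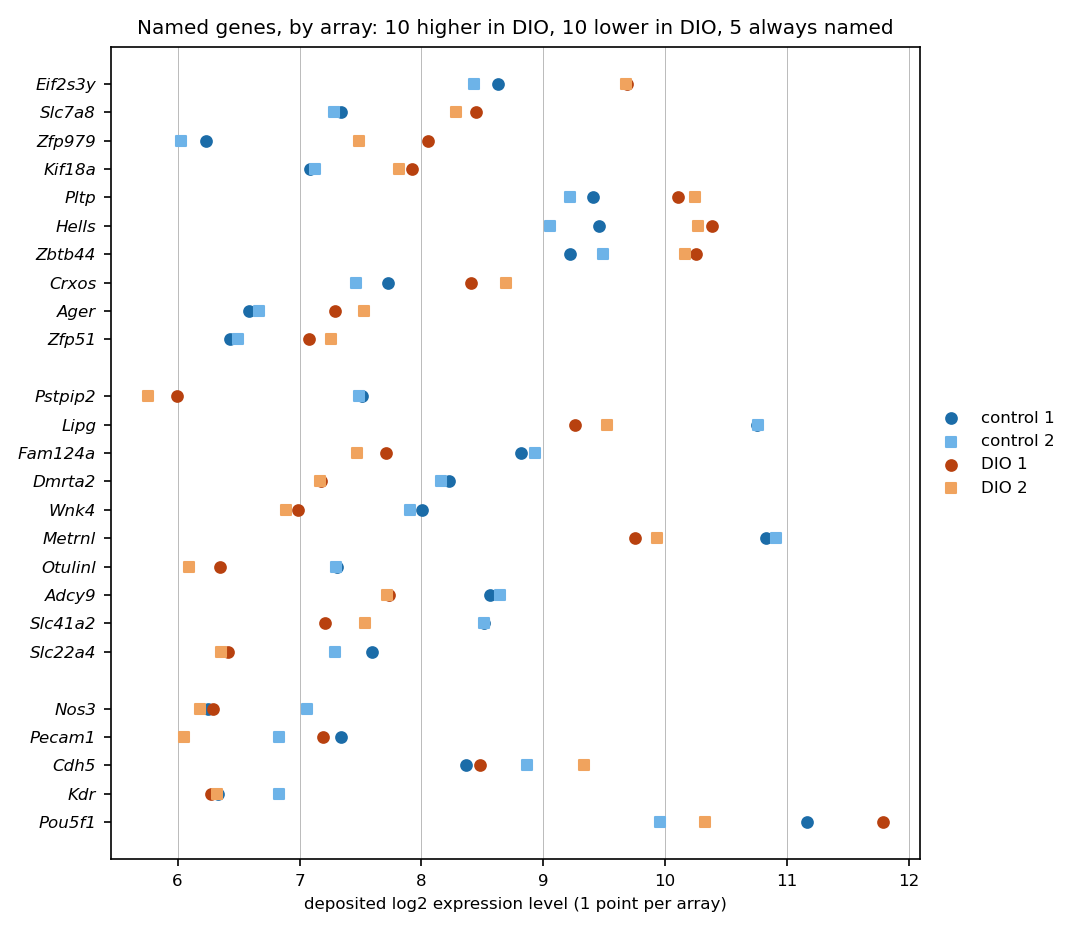
Deposited log2 expression level (horizontal axis) of 25 named genes (vertical axis) on each array, 1 point per array: controls in blue, DIO in orange and red. The first 20 genes were chosen for having both DIO arrays on one side of both controls, as for Lipg at 10.76 and 10.76 against 9.26 and 9.52. Of all genes, 38.4% separate this way, where chance gives 33.3%. Nos3, Pecam1, Cdh5, Kdr and Pou5f1 were named whatever their change, and for them the groups overlap or nearly touch.

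Over all genes, 0 passed the adjusted threshold in limma, and so 0 at a log2 difference of 1 or more. At an unadjusted p below 0.05 there were 1198 genes, 594 higher and 604 lower in DIO, where chance gives 910. Centring each array on its median turned this split to 1072 higher and 327 lower, with the median difference of all genes moving from 0.02 to 0.11, and quantile normalization to 644 and 495. Both DIO arrays lay above both controls for 3898 genes and below for 3090, together 38.4% where chance gives 33.3%. For Zfp979, Uty and Eif2s3y (Uty named after its values were seen) the gap was 1 log2 unit or more upward, and 8 genes had such a gap downward. Leaving out control 1 gave 483 genes past the threshold, 34 higher and 449 lower, and leaving out any other array gave 0. The unadjusted count was 3689 without control 1, 2265 without control 2, 295 without DIO 1 and 171 without DIO 2. An exact 2-sided permutation test of 2 arrays against 2 cannot give a p under 0.333.

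Genes of endothelial identity showed no shift between the groups that passed in the comparison of all 4 arrays. The 28 members averaged 5.77 and 6.04 in the controls and 5.79 and 5.70 in DIO. Tie1, Emcn and Fli1, named after their values were seen, had control means of 3.72, 3.71 and 3.65. Esam, Cdh5 and Egfl7 were brighter, with control means of 8.80, 8.62 and 8.54. The list's averages lay below 7.09, the median of gene means. In control 1, control 2, DIO 1 and DIO 2 the pluripotency list averaged 9.85, 8.87, 10.27 and 9.06. The epithelial list averaged 12.05, 12.28, 12.11 and 12.10. Levels of different probe sets can be set against one another only roughly. The endothelial genes were thus mostly dim beside these lists, but the share of endothelial cells cannot be read from the values. The endothelial list had a median of −0.11 over 28 members (camera, adjusted p = 0.324), with a median of 0.02 without control 2, −0.16 after quantile normalization and −0.01 after centring. It passed without control 1 (median −0.10, adjusted p = 0.0196) but had an adjusted p of 0.847 with an estimated correlation on all arrays. Nos3, the endothelial nitric oxide synthase, was at 6.25 and 7.06 in the controls and 6.29 and 6.19 in DIO, a difference of −0.42 ± 0.31 (limma, adjusted p = 0.788) that became −0.01 without control 2 and −0.83 without control 1. The adhesion molecule Pecam1 differed by −0.46 ± 0.45 (adjusted p = 0.836), and by 0.11 without DIO 2. The junction cadherin Cdh5 differed by 0.29 ± 0.36 (adjusted p = 0.871), by −0.14 without DIO 2 and by 0.04 with its probe sets averaged, of which the other had the opposite sign. Kdr, a receptor for vascular endothelial growth factor, differed by −0.28 ± 0.21 (adjusted p = 0.789), by −0.03 without control 2 and by −0.54 without control 1. Esam differed by 0.14 ± 0.19, and by −0.03 without DIO 2, and Egfl7 by 0.33 ± 0.23, and by 0.07 without control 2. Thbd, which binds thrombin, was at 7.0 and 8.79 in the controls and 7.12 and 7.26 in DIO, and its difference turned from −0.71 to 0.18 without control 2.

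The nitric oxide pathway list, which holds Nos3 and genes that supply or use nitric oxide, had a median of 0.04 over 22 members, a mean of −0.02 and a downward test direction (camera, adjusted p = 0.809). Its median was −0.03 without control 2, 0.15 without control 1, 0.01 without DIO 1 and −0.01 with averaged probe sets. Gch1, the first enzyme of tetrahydrobiopterin synthesis, differed by −0.52 ± 0.17, Qdpr, which recycles it, by 0.08 ± 0.16, the flow-induced transcription factor Klf2 by 0.22 ± 0.46 and the arginine transporter Slc7a1 by −0.05 ± 0.13. None of them passed, and without control 2 Klf2 was at −0.37, Qdpr at −0.03 and Slc7a1 at 0.04. Without DIO 1, Klf2 was at −0.02 and Qdpr at −0.03. Arterial markers (median −0.08, adjusted p = 0.310), with Efnb2 at 0.22 ± 0.19 and Notch1 at −1.06 ± 0.67, and venous and lymphatic markers (median −0.12, adjusted p = 0.485), with Nr2f2 at −0.27 ± 0.43 and Flt4 at 0.39 ± 0.46, passed no test. Without control 2 these genes were at −0.12 for Notch1, 0.32 for Nr2f2 and −0.24 for Flt4, and Efnb2 was at 0.07 without control 1. Nor did vasoactive mediators (median 0.004, mean −0.03, adjusted p = 0.932), angiogenic factors (median −0.13, adjusted p = 0.324) or coagulation genes (median −0.12, adjusted p = 0.779), where the protease inhibitor Tfpi differed by 0.32 ± 0.30, and by −0.08 without control 1. The coagulation median was 0.11 without control 2 and −0.21 without control 1, and the vasoactive median −0.12 without DIO 1.

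Inflammatory cytokine and leukocyte adhesion genes had a median of −0.07 over 29 members (camera, adjusted p = 0.522). Csf1, the macrophage growth factor, was at 8.88 and 8.42 in the controls and 9.73 and 9.63 in DIO, a difference of 1.03 ± 0.20 that did not pass (limma, adjusted p = 0.728), and Nfkbia differed by −0.12 ± 0.13, and by −0.06 without DIO 2. The list's median turned to 0.06 without control 2. Antigen presentation genes had a median of −0.04 (adjusted p = 0.649), with B2m at −0.06 ± 0.15, and at 0.07 without control 1, where the list's median was 0.02. The antioxidant list had a median of 0.09 and a mean of −0.05 (adjusted p = 0.779), and a median of −0.07 without control 2.

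Of the other metabolic and stress lists, oxidative phosphorylation had 26 of 33 members with a higher DIO mean, a median of 0.10 and an adjusted p of 0.0674 by camera. Cox4i1, a subunit of cytochrome c oxidase, differed by 0.29 ± 0.15 and Cox5a by 0.18 ± 0.17, and without control 2 by 0.16 and 0.01. The list's median was 0.02 against control 1, with 18 members higher and 15 lower, and 0.22 against control 2, in which 27 of the 33 were lower than in control 1. This list passed after quantile normalization (adjusted p = 0.0382), after centring (median 0.19, adjusted p = 0.0288), without the dimmest genes (adjusted p = 0.0144) and with averaged probe sets (adjusted p = 0.00734), but not with an estimated correlation (adjusted p = 0.862). Hypoxia response genes had a median of −0.27 (adjusted p = 0.104), with Bnip3 at −0.20 ± 0.37, and at 0.28 without DIO 2. They passed after centring (median −0.18, adjusted p = 0.0288), but not with an estimated correlation (adjusted p = 0.847). Their median was −0.34 against control 1 and −0.07 against control 2, and 18 of the 19 were lower in DIO 2 than in DIO 1, by a median of −0.39, so that the list's median was 0.01 without DIO 2. Glycolysis (median −0.05, adjusted p = 0.485), insulin and IGF signalling (median −0.06, adjusted p = 0.324), p53 response and senescence (median 0.03, adjusted p = 0.779) and TGF-beta and BMP signalling (median −0.01, adjusted p = 0.580) did not pass. In these lists the glucose transporter Slc2a1 differed by 0.01 ± 0.13, Akt1 by −0.03 ± 0.13, Ccng1 by 0.15 ± 0.18 and Id3 by 0.42 ± 0.14. Slc2a1 and Akt1 turned to −0.02 and 0.03 without control 1, and Ccng1 was at 0.04 without DIO 2. Extracellular matrix genes had a median of 0.03 and a mean of −0.10 (adjusted p = 0.779). They passed in opposite directions without either control: upward without control 2 (median 0.24, adjusted p = 0.00141) and downward without control 1 (median −0.45, adjusted p = 3.00e-04). With an estimated correlation on all arrays their adjusted p was 0.933. Imprinted genes had a median of −0.02 (adjusted p = 0.238), with Plagl1 at −0.59 ± 0.15, and positional HOX genes a median of −0.01 and a mean of 0.02 (adjusted p = 0.619). Quantile normalization turned the sign of the median for 2 lists, insulin and TGF-beta. Centring, which added 0.09 to the difference of every gene alike, turned those and 6 more, the arterial, inflammatory, antigen presentation, glycolysis, imprinted and HOX lists. Leaving out 1 array turned the sign of the median for 20 of the 34 lists, 11 of them without control 2, where TGF-beta genes were at 0.10 and HOX genes at 0.09. Medians also turned for p53 genes without control 1 (−0.02), imprinted genes without DIO 1 (0.12), glycolysis genes without control 1 (0.03) and DIO 2 (0.10), and insulin genes without DIO 2 (0.0047). Leaving out 1 array brought further calls: oxidative phosphorylation (median 0.22) and insulin genes (−0.16) without control 1, glycolysis (−0.21) and hypoxia genes (−0.45) without DIO 1, and oxidative phosphorylation (0.12) and imprinted genes (−0.19) without DIO 2. With an estimated correlation on all arrays the adjusted p was 0.847 for insulin and imprinted genes and 0.912 for glycolysis.

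The medians of pluripotency genes differed more within the groups than between them. Pou5f1, which maintains pluripotent cells, was at 11.16 and 9.96 in the controls and 11.79 and 10.33 in DIO, a difference of 0.50 ± 0.67 (limma, adjusted p = 0.881). Dppa5a was at 12.66, 12.07, 13.45 and 12.12 in the same order. The list of 20 had a median of 0.34 (camera, adjusted p = 0.185). All 20 members were lower in control 2 than in control 1, by a median of −1.0, and all 20 were lower in DIO 2 than in DIO 1, by a median of −1.31. The list's median became −0.20 without control 2 and −0.24 without DIO 1, and it passed without control 1 (0.86, adjusted p = 0.00791), without DIO 2 (0.91, adjusted p = 1.51e-09) and without the dimmest genes (adjusted p = 0.04). With an estimated correlation, which was 0.902 for this list, its adjusted p on all arrays was 0.912. The difference of Pou5f1 became −0.10 without control 2 and −0.23 without DIO 1. Spike controls were also higher in both replicate 2 arrays, the poly-A spikes at 7.47 and 8.05 in the controls and 7.41 and 9.08 in DIO, and so was the excess of 3′ over 5′ probe sets, for actin at 0.21 and 0.33 in the controls and 0.25 and 0.30 in DIO.

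**Figure D3:**
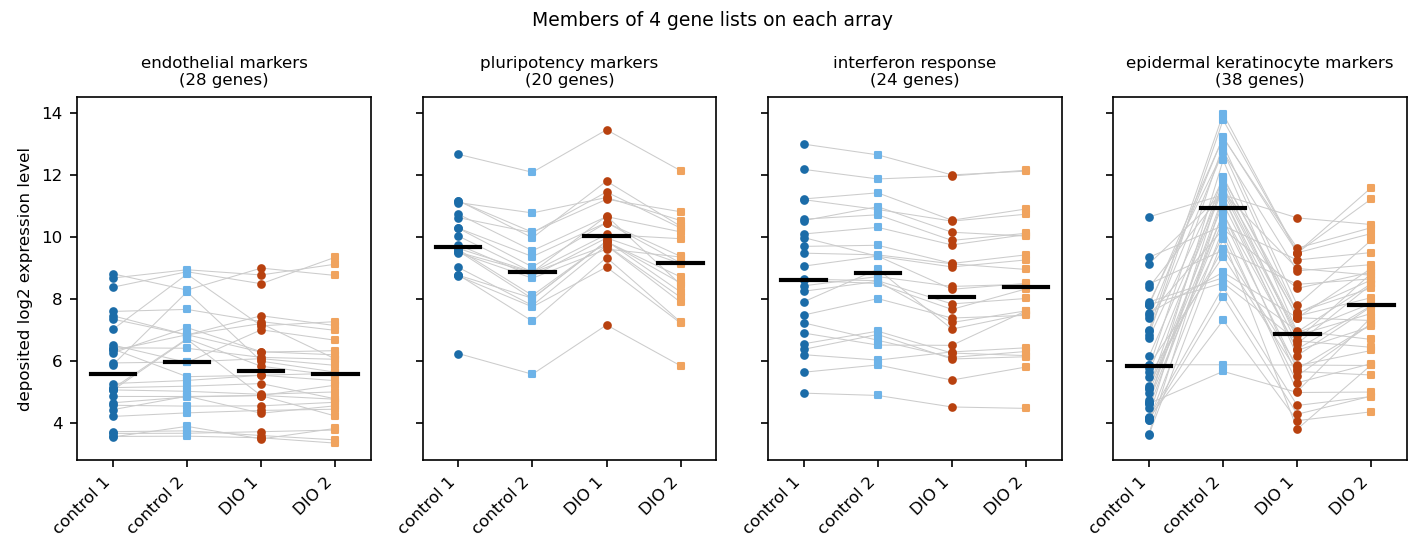
Deposited log2 expression level (vertical axis) of each measured member of 4 gene lists on control 1, control 2, DIO 1 and DIO 2 (horizontal axis); points are genes, grey lines join a gene across arrays and bars are medians. Epidermal markers have medians of 5.81, 10.9, 6.85 and 7.81 on these arrays, and pluripotency markers are lower on control 2 and DIO 2 than on control 1 and DIO 1.

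Among markers of other cell types, Krt8, a keratin of simple epithelia, was at 14.04 ± 0.06 (SD, n = 2) in control and 14.04 ± 0.05 (SD, n = 2) in DIO, and its partner Krt18 differed by 0.07 ± 0.14, and by −0.03 without control 2. The epithelial list had a median of 0.02 and a mean of −0.06 (camera, adjusted p = 0.858), and a median of −0.03 without control 2. Mesenchymal markers had a median of −0.21 (adjusted p = 0.121), with Col3a1 at 7.52 and 10.29 in the controls and 7.35 and 8.46 in DIO, and passed after centring (median −0.12, adjusted p = 0.0288), without control 1 (adjusted p = 7.22e-05) and without DIO 2 (adjusted p = 0.00357), but not with an estimated correlation (adjusted p = 0.847). Against control 1 their median was 0.12, and Col3a1 was 0.39 higher in DIO. Smooth muscle markers had a median of 0.19 (adjusted p = 0.176), with the contractile genes Acta2 and Tagln at 0.91 ± 0.38 and 0.94 ± 0.27, and at 0.39 and 0.60 without control 2. Blood cell (median 0.14, adjusted p = 0.443), cardiac and skeletal muscle (median 0.14, adjusted p = 0.185), neural (median 0.09, −0.01 without control 2 and −0.11 without DIO 1, mean −0.06, adjusted p = 0.961) and adipocyte markers (median 0, mean −0.20, adjusted p = 0.851) did not pass. Endoderm and liver markers had a median of 0.003 and a mean of −0.22 (adjusted p = 0.589), and Gata6, an endoderm regulator, was at 7.72 and 9.31 in the controls and 8.02 and 7.33 in DIO. This list passed without control 1 (median −0.92, adjusted p = 8.89e-04) but not with an estimated correlation on all arrays (adjusted p = 0.912), and Gata6 differed by −0.84, and by −0.04 without control 2. Of the 134 genes taken from the lists, 78 turned their direction when 1 of the arrays was left out, 42 of them without control 2. Of the 97 with other probe sets, 47 had one of the opposite sign, among them Mcm5, Hmgcs1, Fdft1, Hspa5, Xbp1, Hsp90b1, Fabp3, Egfl7, Efnb2, Nr2f2, Slc7a1, Tfpi, Nfkbia, Slc2a1, Akt1, Krt8, Acta2 and Gata6.

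Control 2 stood apart from the other arrays. It held 635 genes more than 1 log2 unit above all other arrays and 55 below, against 15 and 91 in control 1, 7 and 6 in DIO 1 and 5 and 8 in DIO 2. Among them were epidermal genes, a list added after these values were seen: of 38 measured, 37 were highest in control 2. The epidermal keratin Krt10 was at 7.0 and 13.96 in the controls and 9.48 and 11.22 in DIO, and loricrin, Lor, a protein of the cornified envelope, at 6.81 and 13.76 against 9.48 and 11.58. Controls 1 and 2 correlated at 0.963 across genes, which are not independent replicates, and 1164 genes differed at least 2-fold between them. Between control 1 and DIO 1 the values were 0.993 and 212, and between DIO 1 and DIO 2 they were 0.994 and 226.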

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

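The tests on the epidermal genes, the test of interferon against pluripotency genes and the counts for other splits were chosen only after the results were seen. Signals outside the comparison came from control probe sets and from probe sets without a single gene name. The poly-A spike controls, added to the RNA before labelling, averaged 9.08 in DIO 2, above 7.47 and 8.05 in the controls and 7.41 in DIO 1, so that replicate 2 was the higher in both groups. Of 10092 probe sets naming no gene or several, 2 had both DIO arrays at least 1 log2 unit above both controls. The first was at 5.30 and 5.38 in the controls and 6.54 and 6.57 in DIO, and the other at 5.50 and 5.49 against 6.55 and 6.54. As far below both controls lay 5 such probe sets, with the widest gaps at 1.43 and 1.26 log2 units. None of them passed the adjusted threshold in limma, as 0 of these probe sets did, while 1440 had an unadjusted p below 0.05.

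Control 2 stood apart by its epidermal genes. Of 38 measured markers of keratinocytes, 0 of them in the lists fixed earlier, 81.6% lay 1 log2 unit or more above the highest other array, among them the abundant genes Krt10 at 13.96 and Lor at 13.76. Their median excess over the other arrays stayed at 4.27 after quantile normalization. That test could hardly come out otherwise, since the arrays already had similar medians and the list was added after these values were seen. A shift of the whole array is argued against by its median over all probe sets, 5.65 against 5.63 in control 1 and 5.61 and 5.61 in DIO. A difference between control and DIO is argued against, for the list as a whole, by control 1, which lay at a median of −1.19 relative to the DIO mean. Control 1 was the lowest array for 27 of the 38 markers. Some markers were nevertheless higher in both controls than in both DIO arrays. Among them were Ovol1, at 7.80 and 8.51 against 6.64 and 6.43, and Itgb4, at 7.89 and 8.67 against 6.97 and 6.68. Keratinocyte-like cells or their RNA in that sample remain a candidate explanation, with 27 of 38 markers ordered control 1, DIO 1, DIO 2, control 2, and the labels name no sort that would remove such cells.

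The pluripotency genes were lower in the replicate 2 array of both groups, by medians of −1.0 and −1.31. Several RNA measures also differed between the replicates: hybridization spikes were at 10.91 and 11.15 in the controls and 10.69 and 11.19 in DIO, the poly-A spikes were higher in replicate 2 as above, and 3′ minus 5′ signal was higher there for actin (0.21 and 0.33, then 0.25 and 0.30) and Gapdh (0.10 and 0.15, then 0.07 and 0.21). Of 10000 random lists matched on mean level, 0% fell as low in either group, the lowest at −0.51 in control and −0.30 in DIO. Genes of similar level thus did not in general fall as far. This cannot decide on less RNA or weaker hybridization, since the arrays had already been brought to similar scales. Random lists also lack the shared movement of the pluripotency genes, whose estimated correlation was 0.902. Fewer undifferentiated cells in both replicate 2 samples are a candidate explanation. Of 28 further pluripotent cell genes whose values had not been looked at, 25 were lower in control 2 than in control 1 and 24 lower in DIO 2 than in DIO 1, with medians of −0.82 and −0.84. These genes mark the same cell state, so they were likely to fall with the first list. They cannot tell fewer such cells from lower expression in each cell. Loss of particular transcripts was not tested, and it stays open with less RNA and weaker hybridization. More degraded RNA in replicate 2 was not shown, as 3′ minus 5′ signal reached at most 0.33 for actin and 0.21 for Gapdh. The labels give no group that separates these arrays. Both replicate numbers occur in each diet group, and the genes fell within both groups, which argues against diet as the cause of this fall. Between DIO and control the pluripotency list did not pass (camera, adjusted p = 0.185).

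The interferon response genes were lower in DIO by a median of −0.52, a call lost with an estimated correlation (adjusted p = 0.847) and with fry (adjusted p = 0.543), and control 2 alone is argued against by a median of −0.45 relative to control 1. For a difference in the share of undifferentiated cells, the interferon median was taken per unit of the pluripotency median, at −0.09 and −0.14 within the groups. Within them, pluripotency medians of −1.0 and −1.31 came with interferon medians of only 0.09 and 0.19. Between the groups the ratio was −1.56, but −0.56 without control 1 and −0.61 without DIO 2. It had the opposite sign, 2.27 and 1.86, without control 2 or DIO 1, since the pluripotency median itself turned. A ratio that changes sign with 1 array cannot decide the question, so this explanation stays open. This test also replaced a test chosen beforehand, in which replicate 2 minus replicate 1 gave interferon medians of 0.09 and 0.19 and met neither of its bounds. Differences between mice or cell lines unrelated to diet cannot be told apart from DIO: the medians within the pairs, 0.09 and 0.19, were under the bound set beforehand, but that bound was too lenient, since 1 difference between 2 mice in each group does not fix the spread between animals. An effect of diet, and a difference in RNA, with 18S ribosomal RNA at 12.60 and 12.65 in the controls and 12.30 and 11.96 in DIO, stay open beside it and were not tested apart from it.

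At an unadjusted p below 0.05, 1 of the 3 splits of the 4 arrays into pairs, the real one, gave 1198 genes, and the highest of the others gave 922. These splits are too few for a share under 0.05.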

How the results depend on the processing

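Array weights and the run without the 690 genes standing apart in control 2 were chosen after seeing the data. The count of genes past the adjusted threshold, and of those at least 2-fold, was 0 in limma under every alternative except the omission of single arrays, where each ran from 0 to 483. The 483 came without control 1, when control 2 was the lone control and was assumed to vary like DIO; 449 of them stood apart in control 2 and 19 were epidermal markers. The unadjusted count of 1198 was 607 without the dimmest genes (10916 tested, mean level 5.98 or more), 4184 with every probe set, where more features were tested, and from 171 to 3689 with single arrays left out.

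The 6 lists past the threshold became 0 with an estimated correlation, 0 with fry and 2 to 13 with single arrays left out; the cause was not tested. By fry the adjusted p was 0.263 for endoplasmic reticulum stress, 0.41 for fatty acid, 0.587 for sex-linked and 0.862 for proliferation and cholesterol genes. Without control 2, 1 of the 6 lists, interferon response, stayed past the threshold, and the sex-linked list was also lost without the genes standing apart in control 2 (adjusted p = 0.0576). Apart from the estimated correlation and fry, the interferon list passed under all alternatives run on lists, with adjusted p from 2.64e-15 to 5.09e-05. With single arrays left out, Pecam1 ran from −1.03 to 0.11, Cdh5 from −0.14 to 0.72, Pou5f1 from −0.23 to 1.23, and the medians of the endothelial list from −0.0984 to 0.0173 and of the pluripotency list from −0.24 to 0.91; the cause was not tested. Of the values of named genes under the alternatives, 293 kept their direction and side of the threshold, 3 passed and 4 reversed. That side says little where a true log2 change of 1 was recovered in 0% of simulated genes, and averaging probe sets cut the difference of 8 of the 25 genes by over 1.5 times; of the values of the 9 lists followed one by one, the 6 past the threshold and the endothelial, nitric oxide and pluripotency lists, 85 kept the direction and side of their test, 5 passed, 3 reversed and 24 lost their call. Among the 85 the nitric oxide median, at 0.04 against a downward test, turned to −0.01 with averaged probe sets and −0.03 without control 2. Over all 34 lists, 10 gained a call, 23 times in all.

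Both groups share replicate numbers, but nothing says that they pair the mice. Deviations of same-numbered arrays correlated at 0.333 across genes, and 0.214 without the 690 genes. With the replicate block 0 genes passed, 982 had an unadjusted p below 0.05 and 7 lists passed, with the sex-linked list lost (adjusted p = 0.0503) and the pluripotency (adjusted p = 4.96e-04) and mesenchymal lists (adjusted p = 0.0492) gained. Linear alternatives were not run because the values were already log2. Signal over background is unknown, which limits what the values of dim genes show.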

Other observations

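Genes of trophoblast and placenta were read in a list added late, and 8 of its 25 measured genes belonged to lists whose values had already been seen. Of 30 genes, these 25 had medians of 10.58, 10.01, 10.47 and 10.69 in control 1, control 2, DIO 1 and DIO 2. Rhox6 and Rhox9, homeobox genes of the placenta and germ line, were at 13.29, 12.43, 13.17 and 13.39 and at 13.30, 12.36, 13.20 and 13.30. Plac1 was at 11.79, 11.11, 11.95 and 12.39, and Tfap2c, a regulator of trophoblast, at 10.11, 10.10, 10.53 and 11.09. Tpbpa, a marker of spongiotrophoblast, was at 5.89, 4.99, 5.77 and 6.62. No test between the groups was run on this list.

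Single genes outside the naming rule, chosen after their values were seen, separated the arrays in other ways. Trim30a and Trim30d, interferon-induced genes in none of the lists, were at 8.09 and 8.43 in the controls against 6.48 and 6.99 in DIO, and at 6.60 and 6.98 against 5.26 and 5.34. Afp, made by fetal liver and yolk sac, was at 4.29 in control 1, 9.62 in control 2, 5.83 in DIO 1 and 5.72 in DIO 2. The caveolar gene Cav1 was at 5.51, 9.21, 7.45 and 6.59, and Arg1, an arginase, at 6.95, 12.30, 9.93 and 9.79. The Y-linked gene Uba1y was at 7.75, 4.88, 8.05 and 7.64, while Usp9y and Zfy2, also Y-linked, differed between the groups by 0.02 and −0.08. Both were dim, with control means of 3.81 and 5.29 and DIO means of 3.83 and 5.21, so their differences say little.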
